A study of Mus musculus with 4 samples.

How the data were processed

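Myogenic cells were purified from the hind-limb muscle of C57BL/6 mice aged 8 to 12 weeks after injury with cardiotoxin, per the labels, and RNA was prepared from the cells without culture. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy Mini Kit and labelled with biotin by the small sample target labelling assay, version II, of the GeneChip system, and was hybridised to Affymetrix mouse 430A arrays. An assay for small samples amplifies the RNA before labelling, which shortens transcripts and favours probe sets near their 3' end. The labels name the antibody SM/C-2.6 but not the other markers of the purification. How many animals stand behind each sample is not given in the sources used here. The samples fall into 4 groups by day after injury (2, 3, 5 and 14), with 1 array in each.

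The values used are the authors' deposited signal intensities, 1 per probe set and array, on a linear scale from 0 to 15686. Per the submitters' processing notes they were made with MAS5, the Affymetrix algorithm that subtracts mismatch from perfect match probes and can return values near 0 for genes that are not expressed. Its settings and any scaling target are not given in the sources used here, and detection calls were not used here. The medians of the deposited values were 29.6 on day 2, 36.8 on day 3, 53.5 on day 5 and 54.1 on day 14, and their 2% trimmed means 197, 174, 214 and 201, so the arrays as deposited did not share a trimmed mean. No centring was seen, since no value lies below 0. Arrays give no count depth, and their number limits the precision.

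Each array was scaled to the common 2% trimmed mean over its probe sets, with factors of 0.997, 1.13, 0.917 and 0.976 on days 2, 3, 5 and 14. Scaled values under the pooled median of all arrays, 43.0, were set to that floor, log2 was taken and arrays were subtracted. The scaled medians still differed, at 29.5, 41.7, 49.1 and 52.8, and 45.0%, 49.5%, 52.0% and 53.5% of probe sets lay above the floor, so genes of low signal tended to read higher on later days. A gene was called at a ratio of at least 2-fold. A gene at the floor on both arrays was not measured in that comparison, and a ratio with 1 side at the floor is a lower bound. The floor was set before the data were examined, as were the comparisons, lists, rule for named genes and the 9 alternatives.

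Probe sets were named through the platform annotation, which lists 21084 of the probe sets: 20393 had 1 gene symbol, 691 had several and were left out, and 1606 were not named, including 64 control probe sets. The gene ID of 20364 of them was found in the RefSeq table of assembly GRCm38.p6, and no symbol changed. No coordinates are given, since the build of the array design is not given in the sources used here. A gene with several probe sets (4958 genes) was represented by the probe set with the highest mean log2 signal. Levels are compared between arrays for 1 probe set and never between probe sets. Where probe sets of a named gene were far apart, their range is given.

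Day 3 was compared with day 2, day 5 with day 3 and day 14 with day 5, and further day 14 with day 2, day 5 with day 2 and day 14 with day 3. Consecutive comparisons share an array, so a chance value on that array enters both with opposite sign. There is no test, as no day has a replicate. A gene list was described by how many measured members were called and by the median log2 ratio, with its percentile among 10000 random gene lists of the same size drawn with replacement from 20 bins of mean signal, and by a 95% interval from 2000 bootstrap resamples of its members. A list with fewer than 3 measured members was given no median, and ratios at the floor enter at their bound. The percentile describes these arrays alone and treats genes as independent, which genes of 1 pathway are not.

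The 34 lists covered ribosomal proteins, satellite cell quiescence, myogenic regulators, sarcomere and contraction, S phase, G2 and mitosis, growth arrest, Notch, macrophage, neutrophil, lymphocyte, fibroblast, extracellular matrix, endothelial, mural, Schwann cell, erythroid and adipocyte markers, interferon response, MHC class II, immediate early genes, cytokines, oxidative phosphorylation, tricarboxylic acid cycle, glycolysis, fatty acid oxidation, cholesterol synthesis, ribosome biogenesis, unfolded protein response, imprinted genes, IGF, HGF and FGF signalling, TGF-beta and BMP signalling, Wnt signalling and sex-linked transcripts. They overlap, for instance Cdkn1c stands in 3 and Heyl in 2. The list called immediate early genes also covers the response to cell dissociation. Named genes were, per main comparison, the 8 largest increases and the 8 largest decreases among called genes whose measured probe sets all had 1 sign, passing over clones and unnamed transcripts, up to 4 called members of each list, 15 genes given whether called or not, and for single arrays the 6 genes with the largest gap to the nearest other array.

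Alternatives were the values as deposited, quantile normalization, scaling to the median of probe sets above the floor on all arrays, floors at the 25th and 75th percentile, log2 of the signal plus the pooled median with no floor, the mean of all probe sets of a gene, leaving out probe sets named as matching several transcripts, and a 3-fold threshold for the counts, and none was added later. The steps were tested on simulated arrays in which 200 genes were changed by known folds, with noise set to the spread between probe sets. That noise was equal at all signals and was taken from probe sets above the floor on both arrays. It held no spread between animals or labellings. The changed genes were drawn from those above the floor on both arrays. The simulated counts are therefore not the rates of missed or false calls on these arrays. For day 5 against day 3, 25 of 25 genes raised 4-fold and 21 of 24 genes lowered 4-fold were called, while 36 of 6970 unchanged genes were called. For day 3 against day 2 the numbers were 24 of 25, 22 of 25 and 45 of 6852, and for day 14 against day 5 they were 25 of 25, 18 of 24 and 9 of 6996. Genes changed 2-fold lie at the threshold, and for day 5 against day 3, 11 of 25 raised and 10 of 24 lowered ones were called. In the same simulations 3 of 29, 0 of 30 and 0 of 30 unshifted lists fell outside the percentiles at the 3 steps in order of time. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.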

Results

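Gene expression was measured in myogenic cells purified from regenerating mouse hind-limb muscle. The muscle of C57BL/6 mice had been injured with cardiotoxin, a snake venom toxin that destroys muscle fibres and is widely used to set off regeneration, and the cells were taken straight from the muscle without culture. Cells were collected 2, 3, 5 and 14 days after injury and each day was measured on 1 Affymetrix array, so the series holds 4 arrays and no replicates. No difference below has a replicate check, no p-value is given, and a gene is called higher or lower by its size alone, at 2-fold or more between 2 arrays. Signals are MAS5 signals after scaling to a common trimmed mean, in arbitrary units, and a signal under 43.0 (the median of all scaled values) was set to that floor, so that a ratio against a gene at the floor is given as at least N-fold. The probe sets gave 12394 named genes, of which 7930 were above the floor on at least 1 array. Genes above the floor numbered 6258 on day 2, 6874 on day 3, 7251 on day 5 and 7439 on day 14. Between probe sets of 1 gene, the log2 ratio of a single probe set had an SD of 0.36 for day 3 against day 2. This SD was 0.37 for day 5 against day 3 and 0.32 for day 14 against day 5. For day 14 against day 2 it was 0.55, so it can hold more than measurement error within a pair of arrays. It covers probe sets above the floor on both arrays and leaves out the spread between animals and labellings.

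Neighbouring days resembled each other most, and the break lay between day 3 and day 5. Pearson's r of the log2 signals was taken across all genes, which are not independent replicates, with those at the floor on every array included. It was 0.97 between days 2 and 3, 0.94 between days 3 and 5 and 0.96 between days 5 and 14, against 0.84 between days 2 and 14. Over genes above the floor on at least 1 array, the same pairs gave 0.95, 0.90, 0.94 and 0.76. On day 3, 468 genes were at least 2-fold higher and 126 lower than on day 2. On day 5, 874 were higher and 449 lower than on day 3, and on day 14, 371 were higher and 239 lower than on day 5. The split between higher and lower depended on the scaling: 78.8% of the calls of day 3 against day 2 were higher, and 52.6% with the values as deposited, while for day 5 against day 3 the shares were 66.1% and 87.4%, and for day 14 against day 5 they were 60.8% and 50.5%. Over the whole course, day 14 against day 2, 2885 of 7668 measured genes were called. Of 34 gene lists fixed in advance, 29 or 30 had a median at each step. Of these 89 medians, 60 lay outside the central 95% of random lists matched on signal. The 5% outside for random lists is no chance level for these lists. They overlap, hold genes that vary together and are compared over steps that share arrays.

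**Figure D1:**
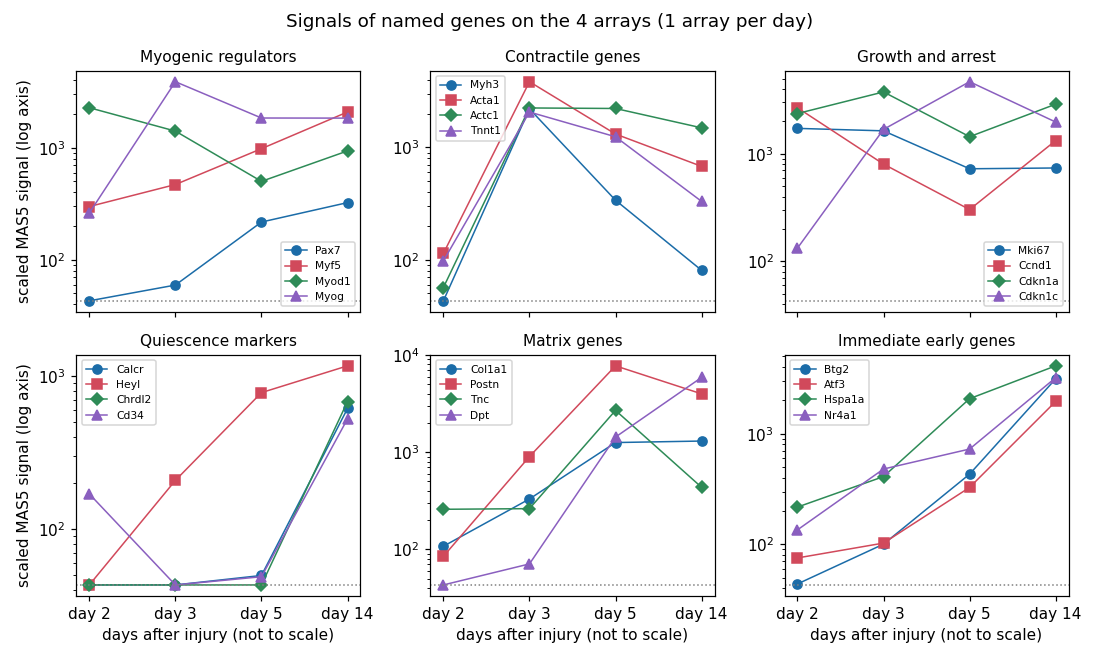
Scaled MAS5 signal (log axis) of named genes on the arrays of days 2, 3, 5 and 14 after injury, 1 array per day, with signals under the floor drawn at the dotted line of 43.0 and days not spaced to scale. Myh3 peaked on day 3 at 2210.1, Tnc on day 5 at 2691, and Calcr on day 14 at 615.

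Day 3 was set against day 2 to follow the first step from proliferating to differentiating cells. Of 42 measured sarcomere and contraction genes, 27 were higher on day 3, none was lower and 15 were not past 2-fold. Their median log2 ratio was 2.39, above all 10000 random lists. Under 8 other settings it ranged from 1.28 to 2.46 and stood apart in each. Myh3, the embryonic myosin heavy chain, went from below the floor to 2210.1, at least 51.5-fold higher, and Acta1, skeletal alpha-actin, from 114 to 3858 (34.0-fold). Mylpf, a fast skeletal myosin light chain, was 44.9-fold higher and Actc1, the alpha-actin of heart and developing muscle, 39.9-fold. The slow troponins Tnnt1, Tnni1 and Tnnc1 were also among the 8 largest increases, at 21.3-fold, at least 18.6-fold and at least 15.3-fold. Of the 42 ratios, 21 had 1 side at the floor.

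The regulators of differentiation stood beside them. Myog, the transcription factor of terminal differentiation, went from 261 to 3876 (14.9-fold), and Mymk, the membrane protein myomaker that myoblasts need to fuse, from 54.0 to 1017 (18.8-fold). Mef2c was at least 2.84-fold higher, and with Myog and Mymk it made up the 3 of 14 measured myogenic regulators that were called (median log2 ratio 0.67, percentile 99.98). Cdkn1c, which encodes the cell cycle inhibitor p57, was 12.7-fold higher, from 133 to 1683, and headed 8 of 24 growth arrest genes that were higher, with none lower. Gadd45g was 3.78-fold, Btg2 2.29-fold and Rb1 2.16-fold higher, while Cdkn1a, which encodes p21, was 1.59-fold higher, short of a call.

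The lists of growth and division genes had lower medians on day 3, with few members past 2-fold. Of 46 S phase genes, 5 were lower and none higher, with a median log2 ratio of -0.41, and among them Gins1 was 2.68-fold lower, Orc1 at least 2.41-fold, Dtl 2.38-fold and Rfc3 2.31-fold. The 57 G2 and mitosis genes had a median of -0.30, with Plk4 2.09-fold lower and Foxm1 2.37-fold higher, although 1 of the 3 measured Foxm1 probe sets gave a log2 ratio of 0.24. Mki67, the Ki-67 proliferation marker, read 1720 on day 2 and 1631 on day 3. Ribosome biogenesis genes had a median of -0.54, 5 of 35 being lower, among them Wdr12 (2.69-fold), Rcl1 (2.68-fold) and Noc4l (2.64-fold). All 3 medians lay below all 10000 random lists. Ribosomal protein genes themselves had a median of 0.02 (percentile 49.19). Ccnd1, which encodes cyclin D1, was 3.34-fold lower.

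The largest decreases on day 3 also held secreted and surface proteins. Cxcl2 and Cxcl1, chemokines that attract neutrophils, were 6.25-fold and 4.21-fold lower, and Ccl2, a monocyte chemokine, 2.75-fold lower, although the median of all 15 measured cytokines and chemokines, -0.18, did not stand apart (percentile 3.06). Cd34, a surface sialomucin of quiescent satellite cells, was at least 3.94-fold lower and was the only lower call of the quiescence markers, of which 7 of 19 were higher (median log2 ratio 0.56, percentile 99.97), among them Cdh15, the adhesion molecule M-cadherin (4.59-fold), and Cdkn1c. The remaining large decreases were Abcb1b, a drug efflux pump (4.33-fold), Rad18, a ubiquitin ligase of DNA damage tolerance (4.26-fold), Paip1 (3.35-fold) and Slc25a33 (3.34-fold).

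Part of the growth factor signalling and matrix genes were higher at this step. Of 18 IGF, HGF and FGF signalling genes, 10 were higher and none lower (median log2 ratio 1.05, above all 10000 random lists), led by Igfbp5 (10.9-fold), which binds insulin-like growth factors, and Igf2 (6.17-fold). Of 37 extracellular matrix genes, 16 were higher and none lower, with a median of 0.92: Col18a1 was 11.2-fold, Col6a2 8.84-fold, Col5a1 7.89-fold and Pcolce 6.72-fold higher. Fibroblast markers had 7 of 16 members higher and none lower (median 0.75, percentile 99.99), with Postn 10.6-fold and Fmod, fibromodulin, 4.29-fold higher. Mural and smooth muscle markers, a list that overlaps with early muscle genes, had 6 of 9 members higher, among them Acta2 (4.79-fold) and Notch3 (3.79-fold, with 1 of its 2 measured probe sets at a log2 ratio of 0.03). Of 15 Notch pathway genes 4 were higher, with Heyl, a Notch target, at least 4.84-fold and Notch1 2.06-fold (median 0.48, percentile 99.36, lost under 1 of 8 other settings). Genes of the immediate early and dissociation response, called immediate early genes here, had 14 of 33 members higher and none lower (median 0.90). Egr1 was 5.10-fold and Ccn1 4.28-fold higher. Immediate early genes respond within minutes to growth factors and stress, and the list also holds heat shock genes such as Hspa1a.

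Day 5 was set against day 3, the step with the most calls. It was marked by matrix genes: of 41 measured extracellular matrix genes, 34 were higher on day 5 and none lower, with a median log2 ratio of 1.92, above all 10000 random lists. Col4a1 and Col4a2, the chains of basement membrane collagen, were 10.5-fold and 9.58-fold higher, Tnc, the glycoprotein tenascin-C, 10.3-fold, from 262 to 2691, and Timp3, an inhibitor of matrix proteases, 8.32-fold, although its 4 measured probe sets ranged down to a log2 ratio of 0.22. Col1a1 went from 330 to 1256 (3.81-fold). Of 21 fibroblast and fibro-adipogenic markers 15 were higher and none lower (median 1.34). They were led by the matrix proteins Dpt (20.2-fold) and Mfap4 (at least 18.8-fold), the aggrecanase Adamts5 (at least 10.2-fold) and Postn, periostin (8.59-fold). Among non-matrix fibroblast markers on day 5, Pdgfra read 105, Cd248 88.9 and Dpep1 48.4. Pi16, Clec3b, Dpp4, Penk, Twist2 and Osr1 lay under the floor, while Gsn read 3542, Serpinf1 2851, Prrx1 651 and Gfpt2 237. The largest single increase was that of Dcx, the microtubule protein doublecortin, at least 24.5-fold to 1052, though its 3 measured probe sets spanned log2 ratios from 0.55 to 4.61. Htra3, a secreted protease (18.7-fold), Fap, a surface protease of activated fibroblasts (18.2-fold), Islr (from 325 to 5856), the growth factor Pdgfc (17.6-fold) and Parm1 (at least 17.2-fold) followed.

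Markers of other cell types and a sign of RNA length differed at the same step. Mural and smooth muscle markers had 6 of 12 members higher and none lower (median log2 ratio 0.97, percentile 99.94), with Tagln, the smooth muscle protein transgelin, 12.5-fold and Pdgfrb, a receptor of pericytes, 4.82-fold higher. Macrophage and myeloid markers had 10 of 20 measured members higher and none lower (median log2 ratio 0.89, 10 of the 20 with 1 side at the floor), with Lyz1 going from 510.3 to 1980.0, Ctss, a lysosomal protease, from 180 to 482, and Csf1r, the macrophage growth factor receptor, from 91.0 to 316, while Ptprc, the pan-leukocyte antigen CD45, read 59.7 on day 5 and lay under the floor on days 2 and 3. The ratio of the 3' to the 5' probe set of Gapdh, a sign of RNA length, was 1.88 on day 3 and 2.87 on day 5, and that of Actb 2.20 and 2.19.

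Most cell cycle genes were lower on day 5. Of 57 G2 and mitosis genes 41 were lower and none higher (median log2 ratio -1.27), and of 45 S phase genes 26 were lower and none higher (median -1.08). The spindle kinesin Kif2c was 5.00-fold lower, the mitotic kinase Plk1 4.44-fold, Shcbp1 4.35-fold and Kif20a 4.33-fold. Among S phase genes the flap endonuclease Fen1 was 3.57-fold, the transcription factor E2f8 3.34-fold, Cdc45 3.19-fold and Mcm10 3.03-fold lower. Mki67 went from 1631 to 725 (2.25-fold lower). Ribosome biogenesis genes had 11 of 35 members lower (median -0.83), among them Nolc1 (2.89-fold), Wdr12 (2.60-fold) and Polr1b, a subunit of RNA polymerase I (2.43-fold). Growth arrest genes went the other way, 10 of 24 being higher and 1, Cdkn1a, 2.60-fold lower, with Btg2 4.30-fold, Gadd45a 2.90-fold and Klf9 2.83-fold higher and Cdkn1c reaching 4667.

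The median of the contractile genes was below 0: of 44 measured, 17 were lower, 1 was higher and 26 were not past 2-fold (median log2 ratio -0.69, below all 10000 random lists). Tnni2, fast troponin I, was 7.09-fold lower, Myh3 6.53-fold, Mybph 6.41-fold and Myh1 6.26-fold, although myosin heavy chains are near-identical copies of each other and their probes can cross-react. Cavin4, a muscle protein of caveolae, was 10.8-fold lower, and Krt8 and Krt18, simple keratins, 10.1-fold and 9.95-fold. Nrcam, an adhesion molecule, was at least 10.1-fold, the mitochondrial protein Chchd10 9.31-fold, the potassium channel Kcnn4 8.44-fold and the phosphatase Mtm1 at least 6.59-fold lower. Lists of energy metabolism had medians below 0, with few members past 2-fold. The 64 oxidative phosphorylation genes had a median of -0.55 with 6 lower, among them Atp5g1 (3.93-fold) and Cycs, cytochrome c (2.36-fold), and the 22 genes of the tricarboxylic acid cycle a median of -0.56 with 5 lower, among them Idh3a (2.86-fold). The 20 glycolysis genes had a median of -0.42 with Eno3, muscle enolase, 5.29-fold lower (percentile 1.19, lost under 2 of 8 other settings), and the 20 fatty acid oxidation genes a median of -0.32 that did not stand apart (percentile 6.40).

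Of 25 quiescence markers 13 were higher and none lower (median log2 ratio 1.13, above all 10000 random lists): Chodl, chondrolectin, was at least 12.0-fold, Gpx3, a secreted glutathione peroxidase, 5.76-fold, Tenm4 5.22-fold and Bmp6 at least 5.01-fold higher. Pax7, the transcription factor of satellite cells, went from 59.4 to 217 (3.65-fold), and Msc, a repressor of MyoD, was 7.95-fold higher. Insulin-like growth factor genes were higher as well: of 18 IGF, HGF and FGF signalling genes 12 were higher and 1 lower (median 1.51), with Igf2 7.54-fold, Igfbp7 7.39-fold, Igfbp3 6.84-fold and Igf1 5.59-fold higher. Of 28 TGF-beta, BMP and myostatin signalling genes 10 were higher and 1 lower (median 0.77), with Tgfb3 7.18-fold, Fstl1 6.81-fold, Bmp1 5.07-fold and Tgfb2 5.01-fold higher. Of 34 immediate early genes, 16 were higher and 1 lower (median 0.92), with Egr2 8.41-fold, Cebpd 6.71-fold, Socs3 5.29-fold and Hspa1a 5.06-fold higher.

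Day 14 was set against day 5 to follow the late step, when regeneration nears its end. Quiescence markers stood out: of 26 measured, 13 were higher on day 14 and 1 lower, with a median log2 ratio of 1.09, above all 10000 random lists. Calcr, the calcitonin receptor that marks quiescent satellite cells, went from 49.5 to 615 (12.4-fold), Chrdl2, a BMP antagonist, from below the floor to 683 (at least 15.9-fold), Cd34 from 48.6 to 526 (10.8-fold) and Bmp6 from 215 to 1437 (6.68-fold). Endothelial cells also carry Cd34, and endothelial markers had a similar median of 1.05, while the probe sets for 18S ribosomal RNA read 1030.1 on day 14 against 2801 on day 5. Bmp4 was at least 22.6-fold higher and led the list of largest increases, ahead of Prelp, a leucine-rich matrix protein (18.9-fold). Rarres2, which encodes the chemoattractant chemerin (at least 11.0-fold), Cp, the copper protein ceruloplasmin (10.8-fold) and the peptide Edn3 (at least 10.8-fold) were among the 8 largest as well. Pax7 read 323 on day 14, 1.49-fold its level on day 5, and the 13 measured myogenic regulators had a median of 0.24 that did not stand apart (percentile 96.71), with Myf5 2.13-fold higher.

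Lists of growth arrest and immediate early genes had medians above 0 on day 14, with most members not past 2-fold. Of 24 growth arrest genes 7 were higher and 1 lower (median log2 ratio 0.41), with Btg2 7.27-fold, Gas6 5.76-fold, Gas1 4.19-fold and Klf9 3.48-fold higher, while Cdkn1c was 2.37-fold lower. Of 17 Notch pathway genes 2 were higher, the target Hey1 (3.54-fold) and Numb (2.51-fold), and the list's median was 0.37 (percentile 99.91). Of 31 TGF-beta, BMP and myostatin signalling genes 7 were higher and none lower, Id3, a target of BMP signalling, being 5.11-fold and Id4 4.72-fold higher. Immediate early genes had 16 of 35 members higher and none lower (median 0.94), with Atf3 5.99-fold, Cebpb 5.21-fold and Maff 5.15-fold higher. Spry1, an inhibitor of FGF signalling, was 2.73-fold higher, but the median of the 19 IGF, HGF and FGF signalling genes, 0.21, lost its place under 6 of 8 other settings and became -0.14 with quantile normalization.

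Medians of the division and contraction lists were again below 0, with most cell cycle genes short of 2-fold. Of 45 S phase genes 9 were lower and none higher (median log2 ratio -0.74), among them the thymidine kinase Tk1 (3.40-fold), the ribonucleotide reductase subunit Rrm2 (2.67-fold), Gmnn, geminin (2.52-fold) and E2f8 (2.51-fold). The 57 G2 and mitosis genes had a median of -0.49 with 5 lower, such as Hmmr (2.31-fold) and Plk4 (2.29-fold), while Mki67 stayed at 737. For Incenp, called 2.26-fold lower, 1 of 2 measured probe sets gave a log2 ratio of 0.31. Against day 2, all 46 measured S phase genes and 51 of 57 G2 and mitosis genes were lower on day 14. Of 41 genes of the sarcomere and contraction list 15 were lower and 1 higher (median -0.57). Tpm1 was 5.89-fold and Mylpf 4.87-fold lower. Muscle genes that are not themselves contractile were lower too, Eno3 5.61-fold and Chrng, the embryonic subunit of the acetylcholine receptor, 5.33-fold. The list of glycolysis genes had a median of -0.36 with 3 of 20 lower, among them Pfkl (2.26-fold).

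Matrix genes split on day 14. Of 41 measured, 3 were higher and 9 lower, and their median log2 ratio of -0.20 did not stand apart (percentile 2.99). Col15a1, a basement membrane collagen, was 9.39-fold higher, while Tnc was 6.19-fold lower, Timp1 4.23-fold and Lox, the enzyme that crosslinks collagen, 3.92-fold. Among fibroblast markers 5 of 23 were higher and none lower, without the list standing apart (median 0.12, percentile 90.06), with Tnxb at least 7.42-fold, Dpt 4.11-fold and Lum 2.20-fold higher. The largest decreases were those of Nt5dc2 (7.77-fold), the desmosomal protein Pkp1 (at least 7.44-fold), Hpgd, which breaks down prostaglandins (at least 7.04-fold), Parm1 (6.60-fold), Has2, a hyaluronan synthase (6.18-fold) and the amino acid transporter Slc38a4 (6.04-fold). Adipocyte markers had 3 of 5 members higher, Fabp4 (7.31-fold), Scd1 (3.94-fold) and Lpl (2.69-fold). Of 222 genes lower on day 14 than on day 5 and also measured on days 2 and 3, 56 had been among the 464 higher on day 3 than on day 2, where independent lists would share 15.2. Of 234 higher on day 14, 27 had been among the same 464, where independent lists would share 16.04. The pairs of arrays have none in common.

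**Figure D2:**
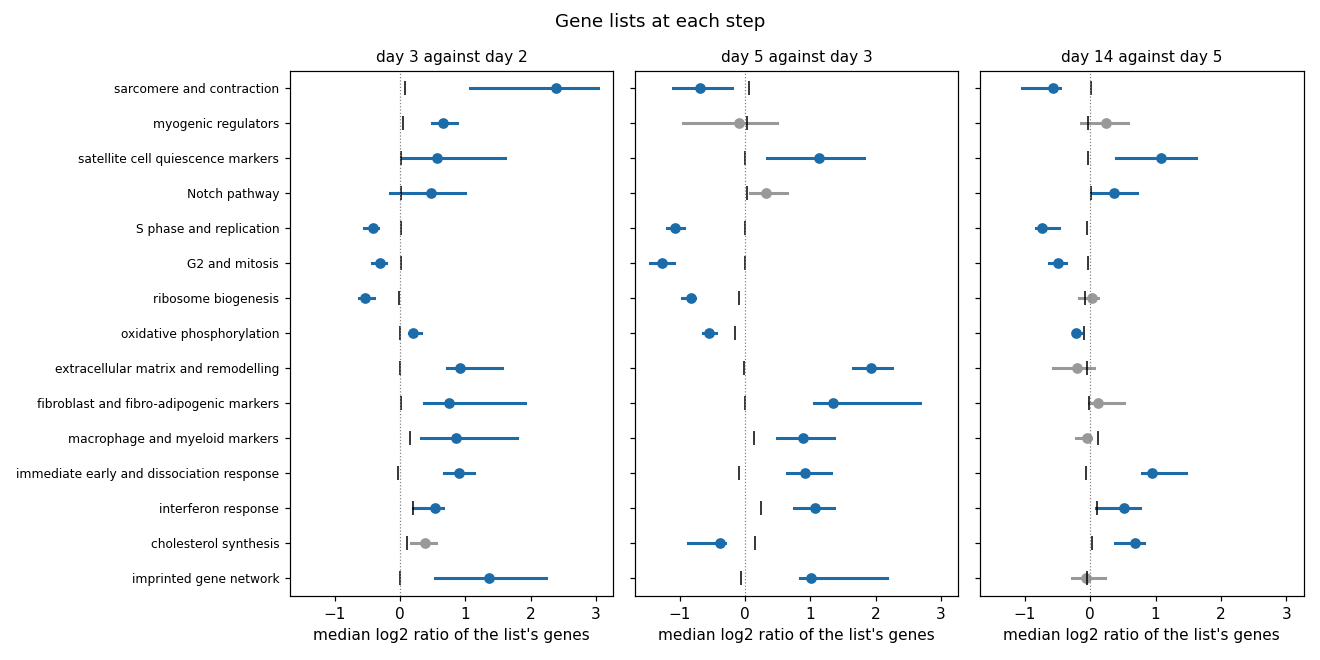
Median log2 ratio of the measured genes of 15 gene lists at each step (horizontal axis), with bars for the 95% bootstrap interval over the list's genes and black ticks for the median of 10000 random lists matched on signal. Blue lists lie outside the central 95% of the random lists and grey lists inside; sarcomere and contraction lies at 2.39 for day 3 against day 2 and at -0.69 and -0.57 at the later steps.

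Followed over all days, the regulators of the myogenic programme traced different courses. Pax7 was under the floor on day 2 and read 59.4, 217 and 323 on days 3, 5 and 14, while Myf5, an early determination factor, read 298, 469, 979 and 2081 on days 2, 3, 5 and 14. Myod1, the determination factor MyoD, read 2272 on day 2, 1405 on day 3, 500.2 on day 5 and 935 on day 14, so that it was lowest on day 5. Myog read 1839 on day 5 and 1835 on day 14, both below its 3876 of day 3. Cdkn1a read 2363, 3751, 1440.1 and 2886 on days 2, 3, 5 and 14. Heyl lay under the floor on day 2 and reached 208, 781 and 1169, and Calcr lay under the floor on days 2 and 3. For Ccnb1, cyclin B1, no probe set named that gene alone.

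Genes that stood apart on 1 array lay mainly at the 2 ends of the course. On day 2, 84 genes peaked and 314 were at their lowest; on day 14, 319 peaked and 92 were at their lowest. Day 3 had 43 peaks and 5 lowest values, and day 5 had 72 and 7. The day 2 peaks with the largest gap to the next array were those of Rad18, Abcb1b, Slc25a33, Hoxa9 (1364 on day 2, 437 at most elsewhere), Zmynd19 and Rcc1, and the lowest values those of Actc1, Cdkn1c, Col18a1, Igfbp5, Postn and Gsn, the actin-severing protein gelsolin. The largest peaks of day 3 were all muscle genes, Tnni2, Myh3, Mybph, Casq2, Mylpf and Tnnt3, and its 5 lowest values were those of Nfkbiz, Cxcl2, Cxcl1, Stk24 and Add3. Day 5 peaked in Parm1, Tnc, Plaat3, Ptgs2, the inducible cyclooxygenase (4.38-fold above the next array), Dcx and Slc6a6, a taurine transporter, and was lowest in Aqp1, Msmo1, Idi1, Ccnd1, Id1 and Cd24a. Day 14 peaked in Bmp4, Prelp, Chrdl2, Calcr, Cp and Edn3 and was lowest in Eno3, Prg4, Limd2, Has2, Nt5dc2 and St8sia2.

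Genes that parted the arrays 2 against 2 mostly split days 2 and 3 from days 5 and 14. In 600 genes both later arrays lay at least 2-fold above both earlier ones, and in 282 the earlier ones lay above. Days 3 and 5 lay above days 2 and 14 in 26 genes, with 1 gene the other way. Days 2 and 5 against days 3 and 14, the parting that follows the wording of the records, took 1 gene. Every main step, day 3 against 2, day 5 against 3 and day 14 against 5, crossed from 1 set of records to the other, so a difference between the sets would enter each of them. Within the sets, day 5 against day 2 gave 2319 called genes and day 14 against day 3 gave 2166.

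Markers of red cells, neutrophils and lymphocytes were under the floor with few exceptions. Median signals of the other cell types below are over markers above the floor on at least 1 array. This choice by itself favours medians above the floor. No erythroid transcript of 6 on the array passed the floor on any day, 13 of 14 neutrophil markers lay under it on every array, with Mmp9 above it on day 5 alone, and 20 of 21 lymphocyte markers did, Thy1 being the exception. The median log2 signal of the 23 macrophage markers ever above the floor was at the floor on days 2 and 3, 6.53 on day 5 and 6.29 on day 14, and day 14 against day 5 had none of 23 called (median log2 ratio -0.05, percentile 4.66). At day 3 against day 2, 5 of 10 measured macrophage markers were higher and none lower (median 0.86, percentile 99.92), led by Lyz1 (5.78-fold), a list that lost its place under 1 of 7 other settings, when probe sets shared between transcripts, as that of Lyz1 can be, were left out. Endothelial markers were at the floor in median until day 5 and at 6.59 on day 14. On day 14, 9 of 17 were higher than on day 5 and none lower, such as Cldn5 (at least 3.44-fold). Aqp1 was 4.72-fold higher than on day 5, but its 346 on day 14 compares with 289 on day 2 and 401 on day 3. Pecam1, the endothelial surface antigen CD31, stayed under the floor on all 4 arrays. It read 4.31 on day 5 and 38.4 on day 14. The 5 endothelial ratios measured on day 3 against day 2 held no call, and on day 5 against day 3, 2 of 7 were higher, with Ramp2 7.66-fold, and 1 lower (median 0.80, percentile 97.68, lost under 5 of 7 other settings). For 23 of 27 fibroblast markers the median log2 signals were 6.18, 6.76, 9.64 and 9.35 on days 2, 3, 5 and 14. Those of 13 of 17 mural markers were 5.42, 6.87, 7.93 and 8.09. Those of 7 of 12 Schwann cell and nerve markers were 5.84, 5.81, 7.10 and 6.94. Those of 5 of 10 adipocyte markers were 6.59, 6.34, 6.60 and 9.47, with day 5 at the level of day 2. Of 5 measured Schwann cell and nerve markers 3 were higher on day 5 than on day 3 (median log2 ratio 1.29, percentile 99.83, lost under 1 other setting).

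Control probe sets gave the quality of the labelling. The 3' to 5' ratio of Gapdh was 2.17, 1.88, 2.87 and 2.84 on days 2, 3, 5 and 14 and that of Actb 1.80, 2.20, 2.19 and 2.14. The hybridisation spikes, added to the labelled sample, had geometric mean signals of 399, 392, 369 and 425 on days 2, 3, 5 and 14. The Y-linked genes Eif2s3y, Kdm5d and Uty lay under the floor on all arrays while Xist read between 569 and 1417.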

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

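All tests in this part were chosen after the results were seen. 2 sets of control probe sets, which no comparison of genes uses, differed between arrays beyond their own spread. The Bacillus subtilis transcripts, which are added to a sample before labelling as poly(A) controls, were higher on days 2 and 5 than on days 3 and 14 by a mean log2 difference of 0.71 (SD over probe sets 0.23), and in the same direction for all 12 probe sets above the floor on every array. Their geometric mean signals were 254 and 239 on days 2 and 5 and 147 and 154 on days 3 and 14. The hybridisation spikes, added after labelling, differed over the same parting by -0.09 (SD 0.15), which argues against the brightness of hybridisation or scanning as the source. The parting follows the 2 sets of records by wording, so that a difference in the amount of control added or in the labelling run may lie behind it, and whether the arrays were run apart is not given in the sources used here. Of the variance of gene signals between arrays, 12.63% followed days 2 and 5 against 3 and 14, the smallest share of the 3 partings, against 72.9% for days 2 and 3 against 5 and 14 and 14.5% for days 2 and 14 against 3 and 5, which argues against that parting as the main source of gene differences; a smaller part in single genes stays open, since each day has 1 array.

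The 3 probe sets for 18S ribosomal RNA read lower on day 14 than on the other arrays, with a mean log2 difference of -1.39 and geometric mean signals of 2639, 2644, 2801 and 1030.1 on days 2, 3, 5 and 14.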

How the results depend on the processing

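The results were recomputed under 9 alternatives, 1 of them for counts alone, and the cause of a shift was not tested unless the construction of the alternative shows it. Of 288 calls of named genes, 170 stayed past 2-fold in every setting that gave the gene a value. Of 60 list medians that stood apart, 47 did so in every setting that gave the list a median. Some had no value under a setting, such as Acta2 on day 3 against day 2 and MHC class II on day 5 against day 3. Settings without a value were left out of these counts, so they are no evidence that a result held there. Of 2943 other values of lists and single genes, 2523 lay within the spread, 418 moved beyond it and 2 turned. The median log2 ratio of IGF, HGF and FGF signalling, day 14 against day 5, became -0.14 with quantile normalization. That of Incenp became 0.31 without probe sets shared between transcripts, where another probe set stood for it.

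With values as deposited, 288 genes were lower on day 3 than on day 2, and 1381 were higher and 199 lower on day 5 than on day 3. The median log2 ratios of S phase and of G2 and mitosis became -0.60 and -0.48 for day 3 against day 2 and -0.77 and -0.96 for day 5 against day 3. Genes peaking numbered 167 on day 2 and 25 on day 3, and 25 were lowest on day 3. The median of all genes went from 0.06 to -0.12 for day 3 against day 2, from 0.06 to 0.33 for day 5 against day 3 and from 0.09 to 0.28 for day 14 against day 3, where 72.5% of calls were higher against 58.6%. Quantile normalization took it from 0.20 to 0.02 for day 14 against day 2, from 0.16 to -0.01 for day 5 against day 2 (52.9% of calls higher against 63.4%) and from 0.09 to -0.02 for day 14 against day 3. It left 209 genes lowest on day 2 and 9 on day 3, and 2 genes parting days 2 and 5 from days 3 and 14.

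A lower floor admits weak signals, and at the 25th percentile 1547 genes were higher and 217 lower on day 3, 1447 and 755 on day 5, and 845 and 468 on day 14, each against the array before. Calls numbered 4447 for day 14 against day 2, 3612 for day 5 against day 2 and 3273 for day 14 against day 3. Genes lowest on day 2 numbered 940. Genes peaking and lowest were 133 and 33 on day 3, and 565 and 140.0 on day 14, with 124 and 22 on day 5. Days 2 and 5 parted from days 3 and 14 in 47 genes, and days 2 and 14 from days 3 and 5 in 82.

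A floor at the 75th percentile left 130.0 higher and 60.0 lower on day 3, 336 and 244 on day 5, and 151 and 100 on day 14. Calls were 1349 for day 14 against day 2, 1047 for day 5 against day 2 and 990.0 for day 14 against day 3. S phase, day 5 against day 3, had a median log2 ratio of -0.90. Peaking and lowest genes were 45 and 82 on day 2, 18 and 2 on day 3, 38 and 1 on day 5, and 136 and 29 on day 14. The partings held 383 genes for days 2 and 3 against 5 and 14, 0 for days 2 and 5 against 3 and 14, and 8 for days 2 and 14 against 3 and 5.

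With the pooled median added to each signal in place of a floor, which shrinks ratios of weak signals, 295 genes were higher and 58 lower on day 3, 295 lower on day 5 and 146 lower on day 14. S phase, day 5 against day 3, had a median log2 ratio of -0.93. Genes peaking and lowest were 35 and 192 on day 2 and 25 and 3 on day 3, and 42 were lowest on day 14. With the mean of all probe sets of a gene, S phase had -0.90 for day 5 against day 3, G2 and mitosis had -0.36 for day 14 against day 5, and 2 genes were lowest on day 3. A 3-fold threshold, which can only lower counts, left 159 higher and 12 lower on day 3, 316 and 85 on day 5, and 131 and 60.0 on day 14, with 1410.0 calls for day 14 against day 2, 967 for day 5 against day 2 and 896 for day 14 against day 3.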

Other observations

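The tests weighed in this part were chosen after the results were seen, and 3 of them were redefined after their own values had been seen. Interferon response genes had a median above 0 at each step. Random lists matched on signal did too, with medians of 0.20, 0.24 and 0.10 at the 3 steps in order of time. For day 3 against day 2, 16 of the 21 interferon ratios had 1 side at the floor. Of 26 measured interferon response genes, 15 were higher on day 5 than on day 3 and none lower (median log2 ratio 1.07, percentile 99.98), with Gbp2, an interferon-induced GTPase, 5.58-fold, the immunoproteasome subunit Psmb8 4.02-fold, the peptide transporter Tap1 3.75-fold and Oasl2 3.57-fold higher. On day 14, 4 of 27 were higher than on day 5, led by Iigp1 (2.92-fold; list median 0.52, percentile 99.98), and on day 3 against day 2, 2 of 21 were higher and Irf1 was 2.13-fold lower (list median 0.53, percentile 98.71, lost under 1 other setting). Of 4 measured MHC class II genes 3 were higher on day 5, H2-Aa 7.55-fold, H2-Eb1 at least 2.62-fold and the invariant chain Cd74 2.61-fold, and on day 14 H2-Ab1 was 2.36-fold higher. Macrophages carry MHC class II, and 10 of 20 macrophage markers were higher on day 5 as well (median 0.89). The cytokine and chemokine list had 5 of 20 members higher and 2 lower on day 5, with Cxcl12 3.31-fold and Ccl7 at least 3.06-fold higher and Il33 2.81-fold lower, and none of 21 called on day 14 (median -0.43, below all 10000 random lists).

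Imprinted genes, a network tied to growth in the embryo, stood apart on day 3 against day 2 and on day 5 against day 3. Of 12 measured, 7 were higher on day 3 than on day 2 and none lower (median log2 ratio 1.37, above all 10000 random lists). Under 8 other settings this median lay between 0.45 and 1.35 and still stood apart. Mest was 5.47-fold and Igf2r 4.09-fold higher, beside Cdkn1c and Igf2. On day 5, 7 of 13 were higher and 1 lower, Plagl1, a zinc finger regulator of the network, being 9.23-fold and Sgce 4.62-fold higher, and on day 14 Meg3 was 3.55-fold higher while Mest was 2.79-fold lower, with no shift of the list (percentile 42.16). Of 19 cholesterol synthesis genes, 4 were lower on day 5 than on day 3 and 15 were not past 2-fold (median -0.38, percentile 0.62, lost under 1 of 8 other settings) and 3 of 19 were higher on day 14 than on day 5 (median 0.68), with Msmo1 3.52-fold lower and then 3.75-fold higher and Idi1 3.36-fold lower and then 2.75-fold higher. Wnt signalling stood apart on day 3 against day 2 with 2 of 15 genes higher (median 0.46, percentile 98.60, lost under 1 of 8 other settings). Of 16 Wnt signalling genes 2 were higher and 1 lower on day 5, among them Fzd4 (2.83-fold), and on day 14 Wnt4 was at least 4.94-fold higher and Ccn4 2.99-fold lower, with medians that did not stand apart at these later steps (percentiles 89.49 and 18.04). The unfolded protein response and chaperone list did not stand apart at any step (2 of 25 higher and 2 lower on day 5), though Asns, asparagine synthetase, was 3.34-fold lower on day 5 and 2.37-fold lower on day 14.

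The higher matrix genes of day 5 raise the question of which cells they came from, and another scaling does not account for them, as the lowest median log2 ratio of the list over the 3 other scalings was 1.90. Fibroblasts or macrophages among the purified cells may have contributed, and the tests of both were redefined after their values had been seen, from counts over hand-picked markers, which were dropped, to medians over all markers above the floor on both arrays, and then to fewer markers. In the earlier form 5 non-matrix fibroblast markers had a median log2 ratio of 0.94 (95% bootstrap interval -0.20 to 1.23) and 10 macrophage markers one of 1.32 (0.78 to 1.61), both intervals wholly below the 1.62 to 2.29 of 37 matrix genes (median 1.92), which by the rule argued against both cell types. Limited to markers at least 2 times the floor on days 3 and 5 and at most 4 times the floor on day 2, because a marker near the floor or already high can hide a small share of cells, 1 fibroblast marker was left, Gfpt2 at 1.12, and 5 macrophage markers with a median of 1.42 (-0.20 to 1.96), which decides neither. Whether matrix transcripts came from myogenic cells or from either of these types stays open, since the verdict depended on the choice of markers and each day has 1 bulk sample, and mural cells, whose markers were also higher on day 5, were not tested.

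The median log2 ratio of the immediate early genes was above 0 at each step, with 14 to 16 of 33 to 35 called higher at a step. On day 14, 31 of 35 were higher than on day 2 (median log2 ratio 3.16). Scaling does not account for this rise, as the lowest median at any step over the 3 other scalings was 0.71. The list was also built to cover the response to cell dissociation, which was not tested as a cause. Heat stress while the cells were isolated could raise such genes, and its test was redefined after its values had been seen: heat shock genes of the list itself, such as Hspa1a, which read 217 on day 2 and 4108 on day 14, were replaced as part of the pattern by 5 chaperones outside it, whose median log2 ratio for day 14 against day 2 was -0.13. Under the rule then in force, a median of 0 or lower, this argued against heat stress. The condition for arguing against it was afterwards made stricter. It then asked that every chaperone be lower, which Hsph1 at 0.20 did not meet. The change was made because chaperone levels were high throughout, Hspa8 reading 9291 on day 2 and 9076 on day 14, so heat stress stays open. A return towards quiescence is a candidate explanation that the quiescence markers allow, with a median of 2.79 over the same days, but any list that was higher on later days would meet that test, and isolation and day cannot be separated with 1 sample per day.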
